A study of Homo sapiens with 6 samples.

How the data were processed

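Gene expression was measured on Affymetrix whole-transcript arrays in MDA-MB-231 cells, an established human triple-negative breast cancer line with mesenchymal features. The deposited table holds 1 value for each of 33297 transcript clusters on each of 6 arrays. A transcript cluster is the group of probes that the array design assigns to 1 locus. Per the labels, total RNA was labelled with biotin using whole-transcript kits. The submitters' processing notes name Affymetrix Expression Console, RMA and the Transcriptome Analysis Console, with no version, role or setting. The values are taken as the log2 expression values that RMA gives, which the authors deposited without a header that states the log base. RMA as commonly run subtracts background, quantile-normalizes the arrays together and summarises probes; values made so lose a shift of all genes in 1 group and compress the changes of dim genes. In the table the array medians lay between 7.47 and 7.51 and no gene was centred. The genome build is not given in the sources used here, and no coordinates are printed.

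Arrays were grouped by their titles into 3 untreated and 3 selamectin arrays. The titles call the controls untreated while the treatment protocol and the design text speak of vehicle, so what the control cultures received is not settled. Array scanner files, detection calls, scan dates and slides were not used here, and no batch could be tested. There is no read depth on an array. The number of arrays limits the precision, and the median standard error of a log2 fold change was 0.094. The design text describes the replicates as independent, with no further account of how the cultures were separated.

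Gene names came from the platform's annotation table, in which 19460 clusters had 1 symbol, 1754 had several and the other 12083 had no entry. Of the clusters with 1 symbol, 19429 were found by Entrez number in a RefSeq gene table (assembly GRCh38.p14, used for names only), and 0 symbols changed. Clusters with several symbols were left unnamed. Where a gene had more than 1 cluster, which was so for 769 genes, the cluster with the highest mean over all arrays stood for it. This left 18417 genes.

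Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), as selamectin minus untreated, two-sided, without a replicate block, with Benjamini-Hochberg adjustment over all 18417 genes and a threshold of 0.05. No filter on dim genes was applied. Means are given ± SD with n = 3 arrays per group, fold changes are linear values of the log2 differences, and intervals are 95% intervals of the fit. Before the data were examined, 34 gene lists were fixed, of which 33 had at least 5 measured members. Mitochondrially encoded transcripts made up the list that had none. The lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over 33 lists, and again with camera at an estimated correlation and with fry (the directional p). The lists share members and are not independent of each other.

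Genes named in the text follow a rule fixed before the data were examined. It takes the 12 largest rises and the 12 largest falls among genes past the threshold whose 3 selamectin arrays all lay on one side of the 3 untreated arrays, skipping small RNA and placeholder symbols. It adds up to 4 members of each list with the smallest p, and a fixed set of genes tied to the SIN3 corepressor. Alternatives fixed at the same time were a second quantile normalization, median centring, filters on dim genes, other eBayes settings, array weights, averaged clusters, a replicate block, leaving out each array, all 33297 clusters, and other thresholds. The array weight came out at 5.11 for untreated array 3 and between 0.45 and 1.22 for the other arrays, so results with array weights lean on that array.

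The fit was tested on simulated data made from the untreated means and the residual spread of each gene as moderated by eBayes, with 200 of 18417 genes changed. It recovered 83% of genes changed by 0.5 log2 units and 100% of those changed by 1 log2 unit, with 4 false calls among 187. That simulation drew genes independently of each other, while genes on real arrays vary together. It also gave every array the same noise and used spreads that the fit had already moderated. Recovery and false calls may therefore look better than on the real arrays.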

Results

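The series compared the transcriptomes of MDA-MB-231 breast cancer cells exposed to 1 µM selamectin for 24 h and of control cells, which the titles call untreated. Selamectin is a macrocyclic lactone of the avermectin family used as a veterinary antiparasitic. The series title frames the compound as an inhibitor of the SIN3 corepressor, a scaffold that brings histone deacetylases to promoters. There were 3 arrays in each group. Over 18417 named genes, arrays of 1 group correlated with r between 0.9949 and 0.9971, and arrays of different groups with r between 0.9913 and 0.9954, taken across genes, which are not independent replicates. The first principal component held 45.8% of the variance and placed all 3 selamectin arrays on the opposite side from all 3 untreated arrays. The second held 20.8% and set selamectin array 3 apart from the other arrays.

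Moderate changes passed the test in a small share of genes after selamectin. Of 18417 genes, 444 rose and 420 fell past an adjusted p of 0.05 in limma, which is 4.69% of those tested. At an unadjusted p under 0.05 in limma there were 3674. With 3 arrays per group, the share that passed is not the share of genes that changed. The median absolute log2 change among the 864 called genes was 0.49, and only 105 rises and 144 falls reached 1.5-fold. A change of 2-fold or more was seen for 5 rising and 9 falling genes. For comparison, the median log2 change of all genes was 0.04 and the median within-group SD was 0.11. The groups did not overlap for any of the 864 called genes, and did not overlap for 25.3% of all genes, where chance gives 10% for a single gene. Genes on the same arrays vary together, so the share over all genes can lie far from 10% by chance. The counts depended on single arrays: they were 76 and 100 without untreated array 1, 140 and 114 without untreated array 3, 96 and 138 without selamectin array 2, 259 and 338 without selamectin array 1, and 685 and 464 without selamectin array 3. When all 33297 clusters entered the fit, 104 rose and 145 fell.

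The largest rise was that of ACTG2, the smooth muscle gamma actin, which went from a log2 value of 7.53 ± 0.07 to 9.32 ± 0.56 (SD, n = 3), or 3.46-fold (log2 change 1.79 ± 0.21 SE, limma adjusted p = 0.0039). Its coding sequence is close to that of other actins, so its cluster may not be specific. HSPB8, a small heat shock protein that works in chaperone-assisted autophagy, rose 2.38-fold from 9.44 ± 0.04 to 10.69 ± 0.22 (adjusted p = 0.0011). ADI1, a dioxygenase of the methionine salvage pathway, rose 2.23-fold, and TRIM29, a tripartite motif protein of basal epithelium, rose 2.05-fold from 8.71 ± 0.04 to 9.75 ± 0.15. LANCL2 rose 2.03-fold, RPP40, a protein subunit of ribonuclease P, 2.00-fold, and CLN6, an endoplasmic reticulum protein altered in a lysosomal storage disease, 1.94-fold. The other leading rises were those of ADM, the vasodilator peptide adrenomedullin, at 1.97-fold, CYP11A1, the cholesterol side-chain cleavage enzyme, at 1.93-fold, MAB21L3 at 1.93-fold, CFAP44 at 1.87-fold and HCAR3 at 1.86-fold. A second, dimmer cluster of CFAP44 changed by 0.15 log2 units and did not pass. HCAR3 has a near-identical neighbour gene, HCAR2, and its value is uncertain for that reason.

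The largest fall was that of ANO2, a calcium-activated chloride channel, which went from a log2 value of 10.92 ± 0.16 to 9.39 ± 0.16 (SD, n = 3), or 2.88-fold lower (limma adjusted p = 0.00058). SLC46A3, a lysosomal membrane transporter, was 2.40-fold lower, and LPL, the lipoprotein lipase that releases fatty acids from triglyceride, was 2.31-fold lower, from 11.07 ± 0.10 to 9.86 ± 0.14. CTH, the cystathionine gamma-lyase that makes cysteine by transsulfuration, was 2.35-fold lower, from 13.55 ± 0.08 to 12.32 ± 0.44, and KYAT1, a cysteine conjugate beta-lyase and kynurenine aminotransferase, was 1.97-fold lower. NEDD9, a scaffold of focal adhesions, was 2.18-fold lower and PRICKLE1, a planar polarity protein, 2.02-fold lower. The others were HSPA2, a heat shock protein of the HSP70 family, at 2.16-fold, MAP2, a neuronal microtubule-associated protein, at 2.01-fold, UNC5A, a netrin receptor, at 2.00-fold, ANXA3, an annexin, at 1.99-fold and ZNF831 at 1.97-fold lower. Of the 24 leading genes, all but ADM, MAP2 and ANXA3 stayed past the threshold whichever array was left out. ADM lost its call without any one array except selamectin array 3 (adjusted p up to 0.16), MAP2 without untreated array 1 (0.084) or untreated array 3 (0.072), and ANXA3 without untreated array 1 (0.062). ADM also lost it without the eBayes trend (0.059), with a robust fit (0.17) and with a replicate block (0.064). With all clusters in the fit, 19 of the 24 passed. Of all 63 named genes that passed, 30 stayed past the threshold whichever array was left out and 33 did not; outside the leading genes, those that did were MUC1, ID2, PMEPA1, MSMO1, ACSS2, OASL, NEU1, SLC2A1 and MMP15, and every other such gene named below lost its call without at least 1 array. In settings that kept all 6 arrays, the fit of all clusters aside, 14 of the 63 lost it: ADM, ST14, SPARC, PDGFRB, JAG1, MMP7, HMGCS1, TOP2A, CDC6, LDHA, ENO1 and TIMP2, each at least with the replicate block, and CYP1B1 and ABCC2 with median-centred arrays.

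**Figure D1:**
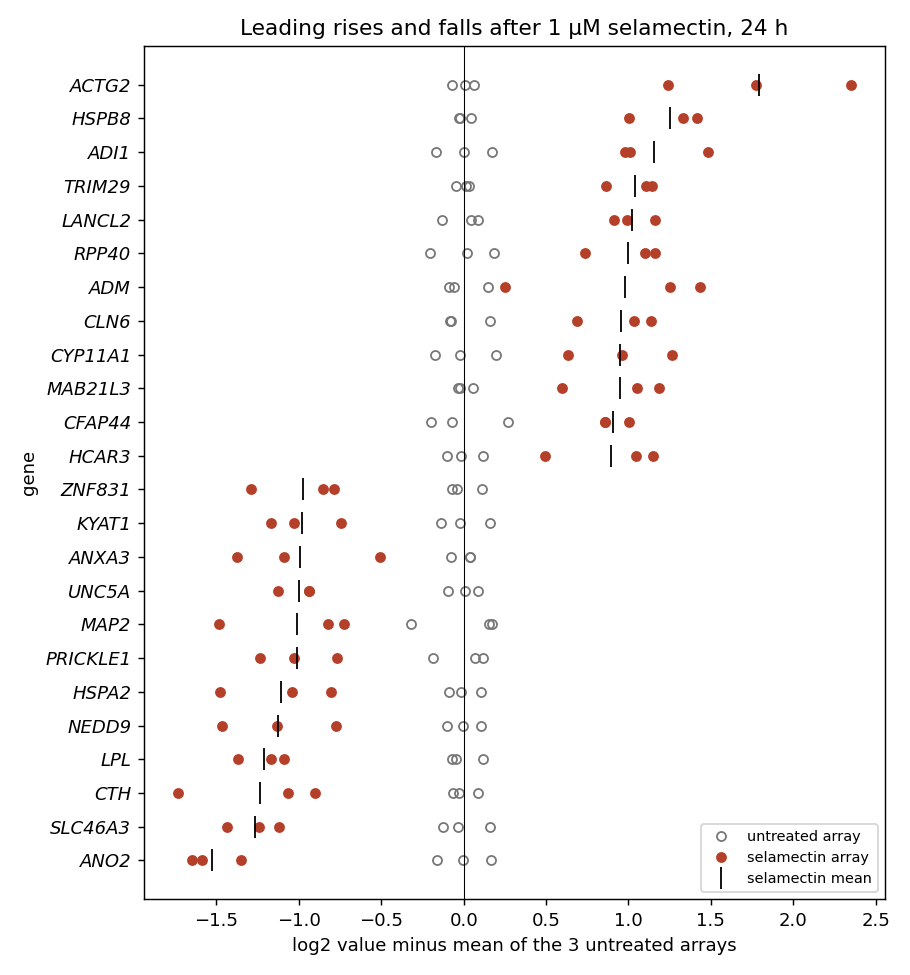
Log2 expression value of each of the 24 leading genes on each array (x axis), minus the mean of the 3 untreated arrays, with 1 gene per line. Open circles are untreated arrays, filled circles selamectin arrays and ticks their mean; the groups do not overlap for any gene shown, and 1 selamectin array of ADM lies close to the untreated range.

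The genes tied to SIN3 inhibition before the data were examined did not pass the test. CDH1, which encodes the epithelial adhesion protein E-cadherin, had a log2 value of 6.27 ± 0.07 untreated and 6.01 ± 0.04 with selamectin (SD, n = 3). Its log2 change was -0.26, with a 95% interval from -0.42 to -0.10 and a limma adjusted p of 0.064. The interval is not adjusted for the number of genes tested and is not used here to exclude a rise. ESR1, the estrogen receptor alpha gene, changed by -0.17 (interval -0.40 to 0.06, adjusted p = 0.41), and its second cluster by 0.002. The corresponding log2 changes were -0.37 for RARB, a retinoic acid receptor (interval -0.77 to 0.03), -0.13 for CLDN6, a claudin of tight junctions (interval -0.32 to 0.05), and 0.04 for SOX2, a pluripotency factor (interval -0.16 to 0.24). SIN3A itself changed by 0.10 (interval -0.08 to 0.29), SIN3B by 0.03 (interval -0.16 to 0.23) and TGIF1, a repressor that recruits SIN3, by -0.23 (interval -0.45 to -0.00196, adjusted p = 0.25). NANOG and POU5F1 lie on clusters with several gene names and were not analysed here. Without detection calls it is not known which of these transcripts were above background. With array weights CDH1 (-0.31, limma adjusted p = 0.0048) and ESR1 (-0.29, adjusted p = 0.037) both passed as lower. The weight of untreated array 3 was 5.11, against 0.66 and 0.45 for untreated arrays 1 and 2. That array held the highest untreated value of both genes (6.34 and 7.16), and the weighted untreated mean rests largely on it. Over the other settings the adjusted p lay between 0.056 and 0.23 for CDH1 and between 0.12 and 0.80 for ESR1.

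**Figure D2:**
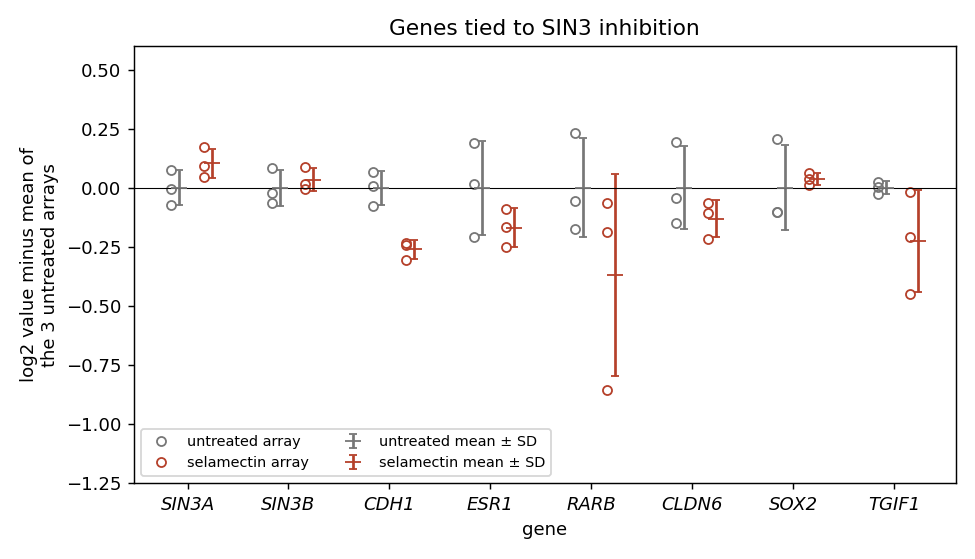
Log2 value of the 8 measured genes tied to SIN3 inhibition on each array, minus the mean of the 3 untreated arrays, with the mean ± SD of each group beside the points (n = 3). CDH1 lies below its untreated arrays on all 3 selamectin arrays and its group means differ by -0.26 log2 units.

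Subunits of the SIN3 complex and its partners showed few changes. Of 25 subunits measured, 1 rose past the threshold, BRMS1, a breast cancer metastasis suppressor, by 0.52 log2 units (limma adjusted p = 0.014), and it was also the only call when adjusted over the list alone. Without passing, HDAC1 stood at 0.29 (adjusted p = 0.10) and ING1, a growth inhibitor family subunit, at -0.27 (adjusted p = 0.17); at an unadjusted p under 0.05, 2 were higher and 1 lower. None of the 15 transcription factors that bind SIN3 passed in limma, over all genes or adjusted over the list alone; at an unadjusted p under 0.05, 2 were higher and 4 lower, with KLF11 at -0.31 and MXD1 at 0.27.

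Markers of epithelial, mesenchymal, luminal and basal breast cells moved in small numbers and in both directions. Of 33 epithelial genes, 2 rose and none fell: MUC1, a membrane mucin, rose 1.80-fold (limma adjusted p = 0.0040) and ST14, the serine protease matriptase, by 0.51 log2 units. Adjusted over the list alone, 3 were higher and 3 lower. Of 38 mesenchymal genes, CD44, the hyaluronan receptor (0.42), and PDGFRB (0.34) rose and SPARC, a matrix protein (-0.45), fell, against 4 higher and 2 lower adjusted over the list alone. Of 27 luminal and estrogen receptor genes, 1 fell, IRS1, the insulin receptor substrate (-0.48), with 2 lower adjusted over the list alone. Of 14 basal genes, 3 rose, TRIM29, KRT5 (0.46) and the laminin subunit LAMB3 (0.50), and adjusted over the list alone 3 were higher and 2 lower. Of 19 stem cell genes, 2 rose over all genes and over the list alone, CD44 and ID3, an inhibitor of helix-loop-helix factors (0.72), while ID1 stood at -0.40 without passing. PDGFRB, which is also a fibroblast marker, was the only call among 12 fibroblast markers. No call was made by limma among 14 leukocyte markers, of which 0 had an unadjusted p under 0.05, or among 12 endothelial markers, of which 2 did.

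Genes of hypoxia and glycolysis were the list with the largest median change. Of 21 measured, 4 rose and none fell: SLC2A1, the glucose transporter GLUT1, 1.80-fold (limma adjusted p = 0.0045), ADM, the glycolytic enzymes LDHA (0.25 log2 units) and ENO1 (0.23). Adjusted over the list alone, 11 were higher. The list's median log2 change was 0.26 and camera gave an adjusted p = 0.00012, against an adjusted p = 0.99 with an estimated correlation and 0.41 in fry. The shift was not shared by all treated arrays: relative to the untreated mean, the list stood at 0.64 on selamectin array 1, 0.51 on array 2 and -0.07 on array 3, where the untreated arrays spanned -0.02 to 0.03. Without selamectin array 3, 16 members rose; without untreated array 2 it was 2 members, and without any one of the other 4 arrays it was 1. The number was also 1 without the eBayes trend or with a replicate block, and 15 with array weights. None of 17 immediate early genes passed in limma (4 at an unadjusted p under 0.05, 1 adjusted over the list alone), with FOS at 0.86 (adjusted p = 0.051). Their list mean was 0.36, 0.23 and -0.21 on the same 3 selamectin arrays.

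Targets of NRF2, the factor that drives antioxidant genes, were called lower as a list only by camera with the preset correlation (adjusted p = 0.00032). The adjusted p was 0.81 in camera with an estimated correlation and 0.18 in fry. Of 17 measured, 2 fell and none rose: SLC7A11, the cystine transporter, was 1.60-fold lower (limma adjusted p = 0.0096), and TXNRD1, a thioredoxin reductase, changed by -0.45 log2 units (0.013). Adjusted over the list alone, 6 were lower. AKR1C3 and AKR1C1, aldo-keto reductases, stood at -0.55 and -0.51 without passing over all genes, and probes for this family can be shared. The list's median was -0.12. All 3 selamectin arrays lay below the untreated arrays in list mean, at -0.23, -0.12 and -0.25. The count of falls was 0 without untreated array 1, 1 without untreated array 3, 4 without selamectin array 3 and 8 with array weights.

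Some genes of cholesterol synthesis and its regulation were lower, while 7 members of the list had a positive log2 change and 11 a negative one. At an unadjusted p under 0.05 in limma, 1 was higher and 6 were lower. Of 18 measured, 4 fell and none rose: MSMO1, a sterol methyl oxidase, was 1.74-fold lower (limma adjusted p = 0.0082), SQLE, squalene epoxidase, changed by -0.55 log2 units, INSIG1, the regulator of SREBP processing, by -0.52, and HMGCS1, the HMG-CoA synthase of the mevalonate pathway, by -0.43. Adjusted over the list alone, 6 were lower. The list's median was only -0.04 while its mean was -0.12; camera gave an adjusted p = 0.021, against an adjusted p = 0.99 with an estimated correlation and 0.18 in fry, and the call was lost with a replicate block (0.054), with array weights (0.096), with either filter on dim genes (0.11 and 0.052), and without untreated array 2 (0.084) or selamectin array 1 (0.14). The count of falls was 1 without untreated array 1 and 2 without untreated array 3 or selamectin array 2. Among 14 fatty acid synthesis genes, 1 fell, ACSS2, the acetyl-CoA synthetase (-0.60, adjusted p = 0.0082), while FASN, the fatty acid synthase, stood at -0.56 (0.053); adjusted over the list alone, 1 was higher and 3 were lower.

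Mitotic genes were called lower as a list only by camera with the preset correlation (adjusted p = 0.0019). The adjusted p was 0.99 in camera with an estimated correlation and 0.35 in fry. The median log2 change of 24 genes was -0.11, and TOP2A, topoisomerase II alpha, was the only one that fell (-0.34, limma adjusted p = 0.048), with none adjusted over the list alone. The list's call was lost without selamectin array 2 (0.053). TOP2A lost its call with median-centred arrays, without the eBayes trend, with a replicate block, and without any one array except selamectin array 3 (adjusted p from 0.058 to 0.19). Among 25 replication genes, 1 rose, the licensing factor CDC6 (0.33), and among 30 histone genes, 1 rose, H2BC14 (0.61), each also the only call adjusted over the list alone. Probes of histone genes can be shared within the family.

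**Figure D3:**
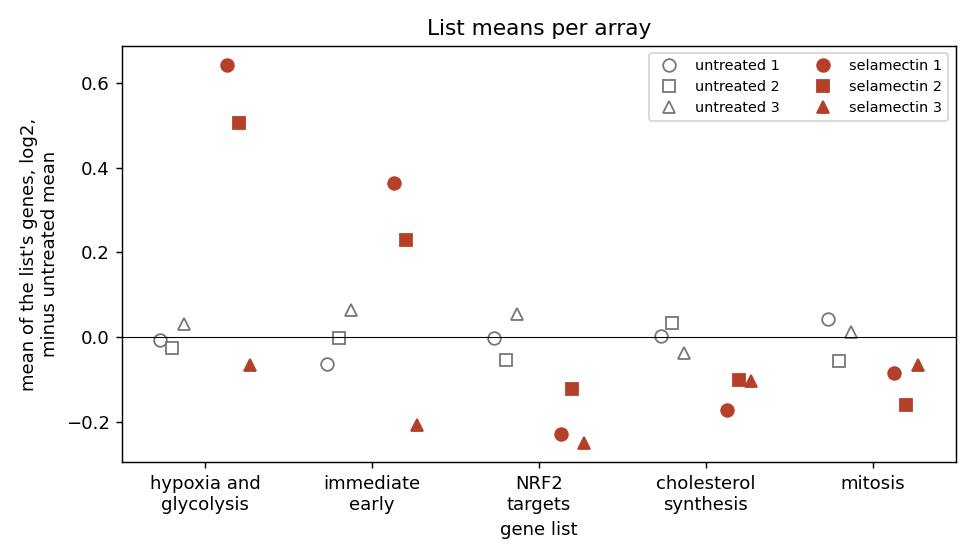
Mean log2 value of the genes of 5 lists on each array (y axis), minus the mean of the 3 untreated arrays; symbols mark the replicate number and filled symbols are selamectin arrays. The hypoxia and glycolysis list lies at 0.64 and 0.51 on selamectin arrays 1 and 2 and at -0.07 on array 3. The NRF2, cholesterol and mitosis lists lie below the untreated arrays on all 3. For mitosis the gap is narrow, with -0.065 on selamectin array 3 against -0.055 on untreated array 2.

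The other lists with calls held between 1 and 5 each. Among 23 TGF-beta targets, NEDD9, ID2 (-0.71) and LTBP3 fell and PMEPA1 (0.56) and ID3 rose, with 2 higher and 4 lower adjusted over the list alone; LTBP3 lies outside the naming rule and was chosen after its value was seen. Among 20 Wnt targets, CD44 and the protease MMP7 (0.37) rose and the Notch ligand JAG1 (-0.37) fell, the same numbers as adjusted over the list alone. Among 27 interferon-stimulated genes, OASL (0.69) and IFIT3 (0.50) rose, with 4 higher adjusted over the list alone. Among 24 NF-kB targets the cytokine LIF rose (0.44), with 3 higher adjusted over the list alone. Among 20 p53 and apoptosis genes MDM2 rose (0.39), also adjusted over the list alone. Among 25 genes of the unfolded protein and integrated stress response, SLC7A11 fell, while DDIT3 stood at 0.61 (limma adjusted p = 0.061); adjusted over the list alone, 2 were higher and 2 lower. Among 14 xenobiotic response genes, the transporter ABCC2 (0.66) rose and ABCC3 (-0.57) and the cytochrome CYP1B1 (-0.55) fell, with 1 higher and 3 lower adjusted over the list alone. Among 22 lysosome and autophagy genes, NEU1, a sialidase (0.64), and ATP6V0D1, a proton pump subunit (0.60), rose and WIPI1, an autophagy protein, was 1.87-fold lower, against 5 higher and 3 lower adjusted over the list alone. Among 19 protease genes, MMP7 rose and MMP15 (-0.66) and TIMP2 (-0.34) fell, the same numbers as adjusted over the list alone.

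The remaining lists held no call in limma over all genes. These were 15 ligand-gated channels and other reported avermectin targets (4 at an unadjusted p under 0.05, with GABRA3 at 0.44), 11 genes often raised by histone deacetylase inhibitors (2, with CDKN1A at 0.40 and TXNIP at -0.62), 9 metallothioneins and zinc response genes (0), 20 ribosomal proteins (2), 20 oxidative phosphorylation genes (2) and 13 expression controls (4, with GAPDH at 0.20 and B2M at -0.25). Adjusted over the list alone, the deacetylase inhibitor list gave 1 higher and 1 lower, the expression controls 2 higher and 1 lower, and the others none. Over all 33 lists, camera with the preset correlation called 4, and neither camera with an estimated correlation nor fry called any; at an unadjusted p under 0.05 these gave 1 and 4 lists. The median, the mean and the camera direction did not share a sign in 10 of the 29 lists that camera did not call, so no direction is given for those.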

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

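The tests of the hypoxia and cholesterol patterns were chosen after the values of those lists were seen. Outside the named genes, a fit of all clusters called 5 clusters with several gene names and 14 clusters with no name as higher in the selamectin arrays, beside 21 and 25 that were lower. In the report they enter only the fit of all clusters, and none of them was analysed by itself.

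The hypoxia and glycolysis list was higher after selamectin by a mean of 0.36 log2 units, but not on every treated array. A rise of the whole list in each treated culture is argued against by selamectin array 3, which lay 0.096 log2 units below the highest untreated array (value -0.096). The authors' normalization stays open: camera gave an adjusted p of at most 0.00030 after either renormalization (adjusted p = 0.99 with an estimated correlation in the unaltered values), but median centring shifted every gene by 0.013 and the second quantile normalization none by more than 0.053 log2 units, so neither could undo it. The range within the selamectin arrays, 0.71, was larger than the difference between groups, which is consistent with variation between cultures, such as density, medium or harvest, that the groups do not explain. An effect of selamectin that differs between cultures stays open and untested. Each of the 4 called genes, SLC2A1, ADM, LDHA and ENO1, was higher on all 3 treated arrays than on any untreated array, with LDHA and ENO1 highest on array 3. The groups did not overlap for any of the 864 called genes, so this separation comes with the call and is no evidence for such an effect.

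The cholesterol list was lower on all 3 treated arrays, with a difference of group means of -0.12 log2 units. The authors' normalization stays open here for the same reason, although camera gave an adjusted p of at most 0.018 after either renormalization (adjusted p = 0.99 with an estimated correlation in the unaltered values). Variation between cultures cannot be told apart from an effect of selamectin: the larger within-group range of the list mean was 0.071, smaller than the difference between groups but too close to it to set them apart. A fall of sterol synthesis genes after selamectin is thus a hypothesis that 3 arrays per group leave open.

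Whether other groupings of the arrays gave as many calls was counted over the 10 ways to split 6 arrays into 3 and 3, which are too few for a share under 0.05. The real split called 864 genes in limma and the highest of the others 0, so 1 of 10 splits gave as many; at an unadjusted p under 0.05 the numbers were 3674 and 1658. For gene lists the real split called 4 with camera at the preset correlation, the highest of the others called 9, and 6 of 10 splits called at least 4.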

How the results depend on the processing

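Of the 24 leading genes, 1, ADM, lost its call in a setting that kept all 6 arrays, the fit of all clusters aside. None of the 63 genes named by the rule that passed changed sign in any setting that refitted them. The counts of higher and lower genes, 444 and 420, stayed within 1.5 times under renormalization, both dim-gene filters, other eBayes settings, averaged clusters and the replicate block (307 and 343). They moved with array weights (1822 and 1464), all clusters (104 and 145, with prior degrees of freedom of 3.53 in place of 7.09), an adjusted p under 0.10 (879 and 723), an unadjusted p under 0.05 with a fold of at least 1.5 (119 and 169) and an adjusted p under 0.05 with that fold (105 and 144). With 1 array left out they ranged from 76 to 685 for higher and from 100 to 464 for lower genes; each such fit has fewer arrays, and the cause of the differences between arrays was not tested. Of those 63 genes, 33 lost the call in at least 1 fit with an array left out and 14 in at least 1 setting that kept all 6. The 4 list calls fell to 0 with an estimated correlation and to 0 with fry, which is a different test, and ranged from 3 to 6 with an array left out. There were 4 uncalled genes that changed sign. With array weights SIN3B went to -0.0395, MT1F to 0.00018 and MT2A to 0.045, and with 1 array left out SOX2 ranged from -0.0145 to 0.14 (-0.0135 without untreated array 1) and MT2A from -0.13 to 0.00668. The alternatives were fixed before the data were examined. The design text names no pairing by replicate number. Deviations from the group means correlated at -0.01, 0.24 and -0.14 for numbers 1, 2 and 3. Only number 2 exceeded 0.1, and not every array correlated best with its own number. With so few arrays these correlations cannot exclude a pairing, and the block is kept as a setting only. Renormalization moved the median log2 change of all genes to at most 0.057, and the share of rises among calls from 51.4% to 48.8% or 57.4%. Detection limits could not be set without scanner files.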

Other observations

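Apart from the planned list of ribosomal protein genes, the tests in this part were chosen after the genes that prompted them had been seen, and before the further lists were tested, although the values of a few list members had been seen; the Fisher's exact test without the prompting clusters and the counts, medians and intervals with arrays left out were added after the result. Genes outside the naming rule are named here after their values were seen. Among the rises stood SRM, spermidine synthase (1.80-fold), SURF2 (1.74-fold), RPP40 (2.00-fold) and UTP4 (1.52-fold), which led to a list of ribosome biogenesis factors without those genes. Of 75 measured, 9 rose and none fell in limma at an adjusted p under 0.05, with 37 higher and 1 lower at an unadjusted p under 0.05. They included the assembly factors PNO1 (0.54 log2 units), NIP7 (0.55), RIOK2 (0.50) and GNL3L (0.51), the nucleolar protein PES1 (0.47), the rRNA methyltransferase NOP2 (0.40) and the nuclease NOB1 (0.34), with WDR74 and UTP14A as the others. The median was 0.24 log2 units (95% bootstrap interval over genes 0.19 to 0.27), while none of 20 ribosomal protein genes was called in limma (2 at an unadjusted p under 0.05). This bootstrap, like those below, resampled genes as if independent on the same arrays. Its interval leaves out variation between cultures and is not the precision of a treatment effect. The number of rises was 0 without untreated array 1, 1 without selamectin array 2, 4 without untreated array 3 and 24 with array weights, while the median stayed between 0.18 and 0.26 in each of these settings. Camera gave an adjusted p = 4.7e-10 over the 3 added lists, against an adjusted p = 0.28 with an estimated correlation, so a general rise of ribosome biogenesis genes (median 0.24) may be present and stays open.

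Clusters named for small RNAs passed as lower more often than as higher. Of 386, none rose and 12 fell in limma, against 444 rises and 408 falls among the other genes (Fisher's exact test on the called genes, two-sided, p = 0.00016, with genes that are not independent). Without the 4 clusters that prompted the test, MIR21, MIR15A, MIR32 and VTRNA1-3, there were 8 falls and no rise among 382 (Fisher's exact test, two-sided, p = 0.0029). The 12 included MIR21 (-0.86 log2 units), MIR15A (-0.85), MIR15B (-0.68), MIR32 (-0.83), the vault RNA VTRNA1-3 (-0.73) and the small nucleolar RNA clusters SNORD38B (-0.74) and SNORA75 (-0.81). At an unadjusted p under 0.05, 10 of the 386 were higher and 74 lower. Direction also differed with brightness over all genes: below the median brightness 68 rose and 119 fell, against 376 and 301 at or above it. The exact tests did not take this into account. When the genes below that median were left out, 124 of the small RNA clusters remained, of which 7 fell and none rose. The number of falls was 4 without untreated array 1, 6 without selamectin array 2, 7 without selamectin array 1, where 1 cluster rose, and 27 without selamectin array 3; with array weights there were 10 rises and 46 falls. A general loss of small RNA signal in the selamectin arrays, for instance through RNA recovery, could not be decided: the other 382 clusters had a median of -0.061 (bootstrap interval -0.11 to -0.04), which straddles the bound of -0.10 set before that median was computed. With 1 array left out that median ranged from -0.03 without untreated array 1 to -0.11 without selamectin array 2. Among the 180 clusters left when the dimmest genes were taken out, the median of all was -0.26, and among the 124 above it was -0.27. Both lie past the bound of -0.10, so the brighter clusters were lower as a set on these arrays. These 2 medians have no interval and can include prompting clusters, and they do not tell the cause. Small RNA clusters can also detect host or precursor transcripts, which was not tested.

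Further lysosomal genes went both ways, which argues against a rise shared by all of them, while a small shift of the list stays open. CLN6, ATP6V0A1 (1.68-fold) and NEU1 rose, while of 46 further lysosomal genes 1 rose, HGSNAT, and 2 fell, GAA and CTSF (10 higher and 8 lower at an unadjusted p under 0.05). No gene of the list rose with any one array left out except selamectin array 3 (2 rises and 2 falls), none was called in either direction without untreated array 1 or untreated array 3, and array weights gave 6 rises and 7 falls. Camera placed the list lower and not higher, without passing, at an adjusted p = 0.33 over the 3 added lists and 0.75 with an estimated correlation. The median was -0.019, and its bootstrap interval of -0.09 to 0.097 lay under the bound of 0.10 set in advance. That bound is not used to exclude a small rise of the median, which was 0.047 (interval up to 0.13) without selamectin array 3.

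A general fall of cysteine and glutathione genes stays open. CTH, KYAT1 and SLC7A11 fell, while of 30 further genes 1 rose, GPX1 (0.70), and 1 fell, GSTM3 (-0.58), with 1 higher and 4 lower at an unadjusted p under 0.05. The counts stayed at 1 and 1 whichever array was left out and were 1 and 5 with array weights. The median was 0.012, with a bootstrap interval of -0.09 to 0.045 above the bound of -0.10 set in advance. Without untreated array 1 the interval reached -0.12, so the bound is not used to exclude a fall.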
